A study of Mus musculus with 9 samples.

How the data were processed

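The series holds 9 samples of total RNA from snap-frozen mouse mammary tumours, 3 from each of the cell lines NDL, Met1 and SSM2. Per the labels, cells were injected on both sides into mammary fat pads of female FVB/NJ mice aged 6 to 8 weeks, and tumours were collected at a width of 5 to 10 mm. RNA was isolated with a Qiagen miRNeasy FFPE kit, and 100 ng was amplified and labelled with the Ambion WT Expression and Affymetrix WT terminal labelling kits. Each sample was hybridised to 1 Affymetrix Mouse Gene 1.0 ST array. The deposited values are log2 signals that the authors made with RMA (oligo 1.40.2), which corrects background, normalises arrays by quantiles and summarises probes. The dates of hybridisation and scanning are not given in the sources used here, so array batches could not be examined.

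The table had 35556 features, of which 21789 carried 1 gene symbol in the annotation used, 1621 several and 12146 none. Features with 1 symbol were kept, with names checked against the RefSeq annotation of GRCm38.p6 (21698 matched, 91 kept their symbol). Where a gene had more than 1 feature (999 genes), the feature with the highest mean over the 9 arrays stood for it. This left 19938 genes, with no filter on signal. Array values have no read depth, so each array is described by its upper quartile. Arrays number 3 per line, which limits the precision.

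The deposited log2 values were fitted without further scaling in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with lmFit and eBayes, no trend and no robust option, on all 9 arrays with 6 residual and 2.42 prior degrees of freedom. Lines were compared with a moderated F-test and 3 two-sided contrasts, each adjusted by Benjamini-Hochberg over the genes, with calls at an adjusted p under 0.05. Errors of log2 differences are the model's standard errors; those of group means are SDs. A gene was called highest or lowest in a line when it passed in both contrasts of that line in the same direction. Gene lists, 36 in number with 656 of 703 entries measured, were tested with camera, with the correlation between genes estimated per list, adjusted over all 108 list tests. A preset correlation of 0.01 and fry were the alternatives. Members were counted in each direction, adjusted over all genes and adjusted over the list alone. RefSeq order served only to group genes by chromosome and to find the neighbours of a gene, and no coordinates are given since the labels name no genome build.

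The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names, per contrast, a few fixed reference genes, the 8 largest differences in each direction among called genes whose arrays do not overlap (leaving out unnamed, receptor-segment and small RNA genes), up to 4 members of each described list with the largest differences, every called member of a list with 5 or fewer calls, and the 6 leading genes in each direction for each line. Of 4 fixed reference genes 3 were measured, and the remaining 1 is not reported here. Members named outside this rule were chosen after their values were seen: Elf5, Wnt5a and Col1a2 and the lower fibroblast genes Col6a1 and Col6a2 between NDL and Met1, Arg1, Lag3, Fads1, Fasn, Csf1 and Egln3 there, Xbp1, Id4, Oxtr, Sqle, Elovl7 and Gpam between NDL and SSM2, and Cdh1, Dusp4, Snai2, Cdh11, Prrx1, Nrg2, Errfi1, Hbegf, Erbb2, Arg1, Dpt, Pdgfra, Col6a1 and Col6a2 between Met1 and SSM2.

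Alternatives were filters on mean signal at the 25th percentile and the median, an intensity trend with robust fitting, cyclic loess, equal medians, array weights, the mean of a gene's features, every feature tested, the replicate number as a block, limma's treat with a minimum fold of 1.5, adjustment over the 3 contrasts together, fits of 2 lines alone, and each array left out in turn. Quantile normalisation, array weights by another method, and leaving out NDL replicates 1 and 2 were added after the data were seen. The procedure was tested on simulated data with known differences. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.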

Results

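Gene expression was measured in 9 mammary tumour samples on Affymetrix Mouse Gene 1.0 ST arrays. There were 3 samples from each of 3 transplantable mouse cell lines, NDL, Met1 and SSM2, all grown in mammary fat pads of female FVB/NJ mice. As background, NDL carries an activated ErbB2 (neu) transgene, Met1 came from a tumour driven by polyoma middle T, and SSM2 is a hormone receptor-positive line. The series title places the data in work on an ErbB2 tumour model for immunotherapy, and the comparisons ask how the lines differ in tumour cell identity, signalling, and immune and stromal transcripts. The labels do not say that samples came from separate animals or separate tumours, so n counts samples and each p measures the spread between them. Values were log2 RMA signals for 19938 genes, and the number of arrays limits their precision. The 4 measured Y-linked transcripts, read here as background in female hosts, lay between 2.61 and 3.85, and the 25th percentile of signal was 4.58. A difference from a group whose mean lies under that percentile has an uncertain size, since it depends on the background. The upper quartile of gene signal was 7.85, 7.84 and 8.09 in NDL replicates 1 to 3, between 8.02 and 8.05 in Met1, and between 7.98 and 8.08 in SSM2. Across genes, which are not independent replicates, arrays of one line correlated at r from 0.947 to 0.986 in NDL, 0.987 to 0.995 in Met1 and 0.962 to 0.983 in SSM2, against 0.891 to 0.949 between lines. The closest NDL pair was replicates 1 and 2 (r = 0.986), and every Met1 pair was closer (r from 0.987 to 0.995). The labels do not exclude that arrays of a line came from one tumour or are technical replicates. In that case the line would have fewer than 3 independent samples. The fit shares 1 estimate of the spread over the 3 lines, so p for every contrast could then be too small. The first principal component held 41.8% of the variance and separated NDL from the other lines, and the second held 29.9% and separated Met1 from SSM2.

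Erbb2 (feature 10380896), the receptor whose activated form drives NDL, stood at 11.30 ± 0.08 in NDL, 7.47 ± 0.28 in Met1 and 8.80 ± 0.16 in SSM2 (log2 signal, mean ± SD, n = 3). NDL was 14.2-fold above Met1 (log2 difference 3.83, SE 0.15, adjusted p = 7.52e-06) and 5.67-fold above SSM2 (2.50, SE 0.15, adjusted p = 3.29e-05), and Met1 was 2.50-fold below SSM2 (-1.32, adjusted p = 0.00114). The arrays do not show whether the signal came from the endogenous gene or a transgene, and the 10 nearest genes with signal above the median of all features differed by a median of 0.59 between NDL and the mean of the other lines. Pgr (feature 10583179), the progesterone receptor, stood at 10.33, 8.85 and 8.74 in the SSM2 arrays, against means of 4.87 in NDL and 4.50 in Met1. It was 21.7-fold lower in NDL than in SSM2 (adjusted p = 0.000151) and lower in Met1 too (log2 difference -4.81, adjusted p = 0.000191), where its mean lay under the 25th percentile of signal. Esr1 (feature 10367600), the oestrogen receptor, was also higher in SSM2, where its mean was 9.10 ± 0.41 (SD, n = 3), than in NDL (7.53 ± 0.17; log2 difference -1.57, adjusted p = 0.00122) and Met1 (6.93 ± 0.07; -2.17, adjusted p = 0.000339). Between NDL and Met1 neither receptor passed the test (Esr1 0.60, adjusted p = 0.0678; Pgr 0.38, adjusted p = 0.522).

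**Figure D1:**
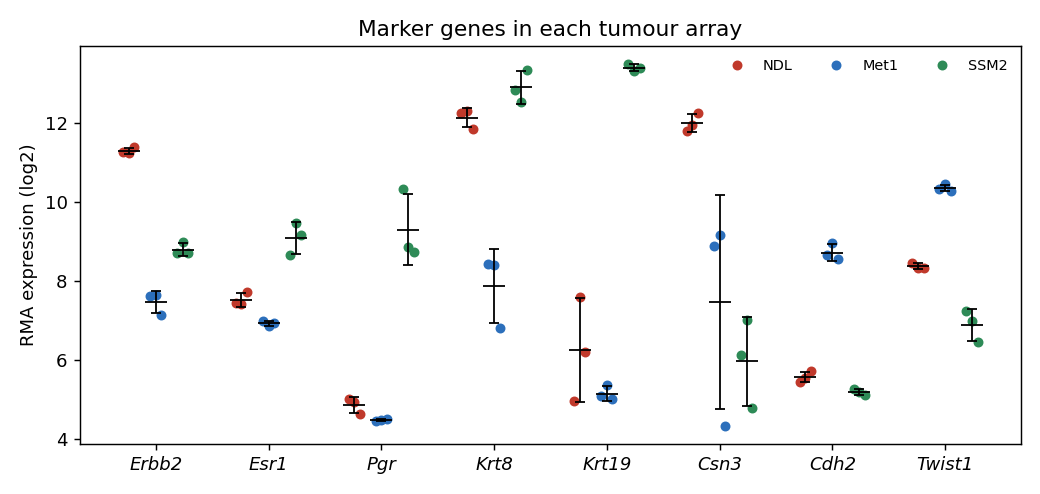
Log2 RMA signal (y axis) of 8 genes in each of the 9 arrays, with NDL in red, Met1 in blue and SSM2 in green; points are arrays, and bars give the mean ± SD of 3. Erbb2 was highest in NDL (11.30), Pgr in SSM2 (9.31) and Cdh2 in Met1 (8.72).

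NDL tumours, compared with Met1 tumours, had higher signal for 20 of 22 epithelial genes, 11 of 18 milk genes and the receptors Erbb2 and Erbb3, and lower signal for 9 of 19 mesenchymal genes. No list passed as a set with an estimated correlation (smallest adjusted p = 0.326). The gene with the largest increase was Chil1, a secreted chitinase-like protein, at 13.48 in NDL and 6.47 in Met1 (129-fold, log2 difference 7.01, SE 0.42, adjusted p = 3.45e-05, n = 3 per line). Apod, which encodes a lipid-binding apolipoprotein, followed at 103-fold (6.68, SE 0.53), with Clca3a2 (6.07), Wfdc18 (5.72), Cd177 (5.38), Ceacam10 (5.34), Fah (5.11), an enzyme of tyrosine breakdown, and Tc2n (5.08, from a Met1 mean of 4.46 near background). Ptgs2, the inducible cyclooxygenase, was lower in NDL by 36.8-fold (5.82 against 11.02, log2 difference -5.20, SE 0.70, adjusted p = 0.00149). Bpifb1 (-4.52), Pcolce2 (-4.27), the bone morphogenetic protein Bmp2 (-4.17, with an NDL mean of 4.06 near background), the pentraxin Ptx3 (-4.14), Tbx15 (-3.80), S100a4 (-3.66) and Tspan6 (-3.61) were also lower. Of 19938 genes tested with limma, 3814 (19.1%) passed an adjusted p of 0.05, 1771 higher and 2043 lower in NDL. At least 2-fold differences numbered 1849, with 783 higher and 1066 lower. The count was 2371 without NDL replicate 1, 6631 without NDL replicate 3, and 2510, 2485 and 2446 without Met1 replicates 1, 2 and 3. Which direction held more genes depended on the scaling: 46.4% of the calls were higher in NDL as deposited and 53.2% after cyclic loess.

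Epithelial adhesion and identity genes were higher in NDL than in Met1 in 20 of 22 measured members, and 21 passed when adjusted over the list alone. Krt8, a keratin of simple epithelia, was 18.9-fold higher (log2 difference 4.24, SE 0.43, adjusted p = 0.000353), the tight junction gene Cldn7 rose by 4.02, Krt7 by 3.59 and Rab25 by 3.58. As a set, the list had an adjusted p = 0.401 with an estimated correlation in camera and 1.17e-14 with the preset correlation of 0.01. Without NDL replicates 1 and 2, whose upper quartiles were the lowest, 16 members were higher. The epithelial list mean stood at 6.64, 6.85 and 5.75 in the Met1 arrays, and the macrophage list mean moved the other way, at 8.15 ± 0.27 in NDL and 8.96 ± 0.20 in Met1 (SD, n = 3). The alveolar and milk genes were higher in 11 of 18 measured members (11 adjusted over the list alone), with an adjusted p = 0.326 with an estimated correlation and 1.92e-08 with the preset one. Among them were the alveolar transcription factor Elf5 (4.05) and the casein genes Csn1s2a (4.89) and Csn1s1 (4.47), whose Met1 means of 3.34 and 3.70 lay in the range of the Y-linked transcripts, so that the size of their differences is uncertain. The casein Csn3 (4.53, adjusted p = 0.0287) stood at 8.90, 9.16 and 4.35 in the Met1 arrays, and its adjusted p was 0.084 without NDL replicate 1 and 0.0752 without NDL replicate 2. Among 16 ErbB receptors and ligands, 5 were higher and 3 lower in NDL (6 and 3 adjusted over the list alone; adjusted p = 0.732 with an estimated correlation). Erbb3, the receptor that partners ErbB2, was 21.9-fold higher (4.45, SE 0.39, adjusted p = 0.000178), and the adaptor Grb7 was higher by 2.53. Hbegf, a ligand, was lower (-1.55), and 1 member was lower without any 1 of NDL replicates 1 and 2, Met1 replicates 1, 2 and 3, or SSM2 replicate 2.

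Basal and myoepithelial genes were higher in NDL than in Met1 in 7 of 20 measured members (7 adjusted over the list alone; adjusted p = 0.914 with an estimated correlation), or 4 without NDL replicates 1 and 2. They included the neural crest and mammary transcription factor Sox10 (3.55), the smooth muscle actin gene Acta2 (2.70), Tagln (2.42) and Id4 (1.76). In the same comparison 8 of 23 fibroblast and matrix genes were higher (5 without NDL replicate 1) and 4 lower in NDL. Met1 replicate 2 was the highest Met1 array for Acta2 (8.35) and Tagln (6.77) as for the matrix genes Col1a1 (11.05) and Thbs2 (8.81). Mesenchymal transition genes were lower in NDL in 9 of 19 measured members and higher in 1, Wnt5a (2.39), a secreted Wnt ligand (10 and 2 adjusted over the list alone; adjusted p = 0.914 with an estimated correlation). S100a4 (-3.66), the N-cadherin gene Cdh2 (-3.14, SE 0.13, adjusted p = 7.52e-06), the receptor kinase Axl (-2.50) and the repressor Zeb1 (-2.40) had the largest falls. The number of higher members was 4 without NDL replicate 3 and 2 without Met1 replicate 2. Genes known as outputs of ERK signalling went both ways, with 4 of 20 higher, among them Dusp4 (2.23) and Epha4 (1.35), and 4 lower, among them Fosl1 (-2.49) and Spry2 (-1.42), with 5 and 4 adjusted over the list alone (adjusted p = 0.94 with an estimated correlation). Without SSM2 replicate 3, 7 were higher.

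NDL and SSM2 tumours had epithelial list means of 8.99 ± 0.10 and 9.55 ± 0.09 (SD, n = 3) and differed in single mammary epithelial genes. Krt19, a keratin of simple epithelia, was 141-fold lower in NDL (6.26 ± 1.31 against 13.40 ± 0.08, SD, n = 3; log2 difference -7.14, SE 0.53, adjusted p = 9.33e-05). Itih2, a plasma protease inhibitor heavy chain, was 127-fold lower (-6.99, SE 0.25, adjusted p = 4.32e-06). Sprr1a (-6.07), a gene of the cornified envelope, Tph1 (-5.70), a tryptophan hydroxylase, Clca1 (-5.50), Capsl (-5.28) and D17H6S56E-5 (-4.67) were also lower. Higher in NDL were the carbonic anhydrase Car2 (49.1-fold, log2 difference 5.62, SE 0.31, adjusted p = 2.06e-05), Wfdc18 (5.64), Clca3a2 (5.37), Ceacam10 (5.35), Cd177 (5.33) and Chil1 (5.27), and Tc2n (adjusted p = 0.00025), whose SSM2 mean of 3.52 lay in the range of the Y-linked transcripts. In limma 3364 genes (16.9%) passed, 1865 higher and 1499 lower in NDL. At least 2-fold differences numbered 1542, of which 744 were higher and 798 lower, and 2582 without NDL replicate 3. Leaving out NDL replicate 1 gave 1873 genes, NDL replicate 2 gave 2182 and NDL replicate 3 gave 7018.

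Alveolar and milk genes were higher in NDL than in SSM2 in 14 of 18 measured members (15 adjusted over the list alone; adjusted p = 0.326 with an estimated correlation, 4.27e-09 with the preset one). Csn3 was 64.9-fold higher (log2 difference 6.02, SE 1.17, adjusted p = 0.0103), and Elf5 rose by 4.64. Csn1s2a (4.92) and Csn1s1 (4.32) were higher too, from SSM2 means of 3.32 and 3.85 in the range of the Y-linked transcripts. Outputs of ERK signalling were higher in 12 of 20 measured members (14 adjusted over the list alone; adjusted p = 0.401 with an estimated correlation, 8.64e-06 with the preset one), and in 6 without NDL replicates 1 and 2. The ETS factors Etv1 (19.7-fold, 4.30, SE 0.29, adjusted p = 5.52e-05) and Etv5 (3.49), Phlda1 (3.26) and the feedback inhibitor Spry4 (2.53) rose most. Hormone-sensing luminal genes were lower in NDL in 7 of 18 measured members and higher in 1, the secretory pathway factor Xbp1 (0.92); adjusted over the list alone these were 8 and 3 (adjusted p = 0.581 with an estimated correlation). Beside Pgr (-4.44) they included the pioneer factor Foxa1 (-3.67) and Cited1 (-3.03). The chemokine gene Cxcl15 (-6.33, adjusted p = 0.016), whose NDL mean of 4.24 was near background, stood at 12.76, 12.33 and 6.64 in the SSM2 arrays, and its call ended without NDL replicate 1, NDL replicate 2 or SSM2 replicate 2, with adjusted p from 0.0507 to 0.0566. Higher hormone-sensing members numbered 5 without NDL replicate 3 and 2 without SSM2 replicate 1.

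Basal and myoepithelial genes were lower in NDL than in SSM2 in 9 of 20 measured members and higher in 3, Sox10 (3.61), Id4 (1.67) and Oxtr (0.77), with the same 9 and 3 counts adjusted over the list alone (adjusted p = 0.914 with an estimated correlation). The lower members were led by stratified keratins, Krt15 (-4.20) and Krt14 (-4.07), and by Krt5 (-4.62, adjusted p = 0.0156), whose adjusted p was 0.0522 without NDL replicate 1 and 0.0552 without SSM2 replicate 2. Of 22 epithelial adhesion and identity genes, 4 were lower and 1 higher in NDL (4 and 2 adjusted over the list alone): Krt19, the tight junction genes Cldn4 (-2.58) and Ocln (-1.16), Muc1 (-1.74) and, higher, Ovol2 (0.58). The Muc1 call (adjusted p = 0.0421) ended in 7 of 9 fits with 1 array left out (adjusted p from 0.0536 to 0.127), all but those without NDL replicate 3 or SSM2 replicate 3. Without SSM2 replicate 3, 2 epithelial members were higher. Cholesterol synthesis genes were higher in NDL in 8 of 18 measured members and lower in 2 (10 and 3 adjusted over the list alone; adjusted p = 0.914 with an estimated correlation). The reductase Dhcr7 (2.18), the regulator Insig1 (1.69) and Lss (1.42) rose, and Hmgcs1 (-1.87) and Sqle (-1.25), enzymes of earlier steps, fell. The higher members numbered 5 without NDL replicate 2 and 4 without NDL replicates 1 and 2, and the lower members 5 without NDL replicate 3.

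Met1 tumours, compared with SSM2 tumours, had lower signal for 21 of 22 epithelial, 9 of 20 basal and 7 of 18 hormone-sensing genes, lists that each had an adjusted p = 0.326 with an estimated correlation. Krt19 was 303-fold lower (5.16 against 13.40, log2 difference -8.24, SE 0.53, adjusted p = 7.99e-05, n = 3 per line). Itih2 was 115-fold lower (-6.85, SE 0.25, adjusted p = 1.21e-05), and Cxcl15 (-6.89), Sprr1a (-6.30), Tph1 (-5.88), Clca1 (-5.77), Capsl (-5.59) and Wnt5a (-5.51) fell too, of which Cxcl15, Tph1 and Capsl had Met1 means of 3.68, 4.54 and 4.34, near background. Higher in Met1 were Mme, the membrane peptidase neprilysin (30.8-fold, 4.94, SE 0.71, adjusted p = 0.00315), Bpifb1 (4.66), Etv1 (4.50), the integrin Itga8 (4.00), Trib2 (3.97), Ptx3 (3.96), the Wnt inhibitor Wif1 (3.81) and Stac2 (3.79). In limma 2356 genes (11.8%) passed, 1416 higher and 940 lower in Met1. At least 2-fold differences numbered 1212, of which 672 were higher and 540 lower. The count was 1360 without Met1 replicate 1 and 1436 without Met1 replicate 2.

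Epithelial adhesion and identity genes were lower in Met1 than in SSM2 in 21 of 22 measured members (21 adjusted over the list alone; adjusted p = 0.326 with an estimated correlation, 1.11e-26 with the preset one). Beside Krt19 the largest falls were in Cldn4 (-5.04), Krt8 (-5.01) and Krt7 (-4.40), and the E-cadherin gene Cdh1 fell by 3.42. The mean of the list was 6.64, 6.85 and 5.75 in the Met1 arrays, against 9.55, 9.47 and 9.64 in SSM2. The macrophage list mean moved with it the other way, at 8.96 ± 0.20 in Met1 and 8.33 ± 0.57 in SSM2 (SD, n = 3). Hormone-sensing luminal genes were lower in 7 of 18 measured members (9 adjusted over the list alone; adjusted p = 0.326 with an estimated correlation, 2.66e-06 with the preset one), with Pgr (-4.81), Foxa1 (-3.66) and Myb (-3.53) among them. Basal and myoepithelial genes were lower in 9 of 20 (11 adjusted over the list alone; adjusted p = 0.326 with an estimated correlation, 8.08e-10 with the preset one), led by Krt15 (-4.49), Krt14 (-4.25) and Krt17 (-3.33). Krt5 stood at -2.96 and did not pass (adjusted p = 0.0993).

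Outputs of ERK signalling were higher in Met1 than in SSM2 in 10 of 20 measured members and lower in 1, Dusp4 (-1.25), a phosphatase that acts on ERK (12 and 2 adjusted over the list alone; adjusted p = 0.401 with an estimated correlation, 8.64e-06 with the preset one). Etv1 (4.50), the feedback inhibitor Spry2 (3.18), Etv5 (2.82) and Phlda1 (2.70) had the largest rises, and 2 members were lower without SSM2 replicate 1. Mesenchymal transition genes were higher in 8 of 19 and lower in 4 (9 and 6 adjusted over the list alone; adjusted p = 0.914 with an estimated correlation). Cdh2 (11.5-fold, 3.53, SE 0.13, adjusted p = 1.21e-05), the transcription factor Twist1 (3.46) and S100a4 (3.19) were higher, while Wnt5a (-5.51), Snai2 (-1.94), Cdh11 (-1.69) and Prrx1 (-1.38) were lower; 2 members were lower without Met1 replicate 1. The fibroblast and matrix list mean was lower in Met1 too, at 8.25 ± 0.35 against 9.07 ± 0.65 in SSM2 (SD, n = 3). Among 16 ErbB receptors and ligands, 4 were lower in Met1, Erbb3 (-4.05), the ligand Btc (-2.86), Grb7 (-2.64) and Erbb2, and 3 were higher, Hbegf (1.68), Nrg2 (1.08) and Errfi1 (0.72). Adjusted over the list alone these were 6 and 4 (adjusted p = 0.581 with an estimated correlation). Cholesterol synthesis genes were higher in 7 of 18, among them Insig1 (1.31) and Dhcr7 (1.25), and lower in 1, Sqle (-1.19). Adjusted over the list alone these were 8 and 1, with an adjusted p = 0.732 with an estimated correlation, and the higher members numbered 3, 4 and 3 without Met1 replicates 1, 2 and 3 and 3 without SSM2 replicate 1.

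**Figure D2:**
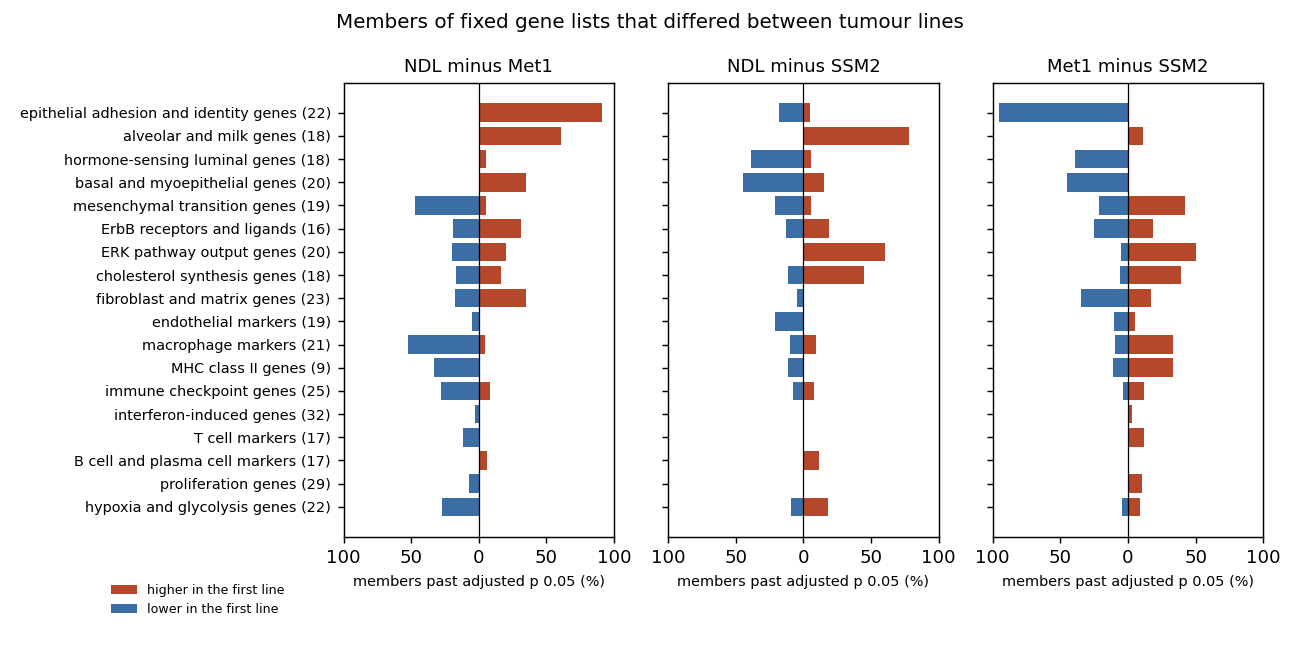
Percent of measured members (x axis) of 18 gene lists (y axis) that passed an adjusted p of 0.05 in limma, higher in the first line (red, to the right) or lower (blue, to the left), with 1 panel per comparison of 3 arrays against 3. Epithelial genes passed in 20 of 22 members between NDL and Met1 and in 21 of 22 between Met1 and SSM2.

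Macrophage markers were lower in NDL than in Met1 in 11 of 21 measured members and higher in 1, Arg1 (2.01, adjusted p = 6.38e-05), the arginase of alternatively activated macrophages (14 and 2 adjusted over the list alone; adjusted p = 0.914 with an estimated correlation). The fractalkine receptor Cx3cr1 (-2.18), the scavenger receptor Msr1 (-2.11) and the mannose receptor Mrc1 (-2.02) fell most. The lower members numbered 3 without NDL replicate 1, 7 without NDL replicate 3, 3, 4 and 3 without Met1 replicates 1, 2 and 3, and 2 without NDL replicates 1 and 2. The higher members numbered 2 without NDL replicate 3 or SSM2 replicate 3. Between Met1 and SSM2, 7 macrophage markers were higher in Met1, led by Cx3cr1 (2.29), and 2 were lower, the haemoglobin scavenger receptor Cd163 (-2.94) and Arg1 (-0.69); adjusted over the list alone these were 11 and 2 (adjusted p = 0.914 with an estimated correlation). The higher markers numbered 4 without NDL replicate 1, then 2, 2 and 1 without Met1 replicates 1, 2 and 3, and 11, 2 and 3 without SSM2 replicates 1, 2 and 3. The lower markers numbered 1 without Met1 replicate 1 or 2. Between NDL and SSM2, Cd163 and Mrc1 were lower in NDL (-2.31 and -2.14), and Arg1 (1.32) and the lipopolysaccharide co-receptor Cd14 (1.89, adjusted p = 0.0379) were higher. The Cd14 call ended without NDL replicate 1, NDL replicate 2 or any 1 Met1 array (adjusted p from 0.0602 to 0.129), which left 1 higher marker, and 4 were higher without NDL replicate 3.

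MHC class II genes were lower in NDL than in Met1 in 3 of 9 measured members, H2-Ob (-1.08, adjusted p = 0.00115), H2-Ab1 (-1.11, adjusted p = 0.0488) and the cathepsin Ctss (-1.07, adjusted p = 0.037), and in 5 adjusted over the list alone (adjusted p = 0.914 with an estimated correlation). The class II list mean moved with that of the macrophage markers, at 8.47 ± 0.35 in NDL and 9.40 ± 0.115 in Met1 against 8.15 ± 0.27 and 8.96 ± 0.20 (SD, n = 3), and within each line the arrays ranked in the same order in both. The H2-Ab1 and Ctss calls each ended without NDL replicate 1, any 1 Met1 array or SSM2 replicate 2 (largest adjusted p 0.168 and 0.13, both without NDL replicate 1). H2-Ab1 lost its call without NDL replicate 3 too, and Ctss without NDL replicate 2. The lower members numbered 1 without NDL replicate 1, Met1 replicate 1, 2 or 3, or SSM2 replicate 2, and 5 without SSM2 replicate 3. H2-Eb1, a class II beta chain, stood apart in SSM2 at 11.33, 10.26 and 9.62. It was lower in NDL (-3.48, adjusted p = 0.000733) and in Met1 (-2.66, adjusted p = 0.0035), while the other class II gene calls between Met1 and SSM2, H2-Ob (1.10), Cd74 (1.44) and Ciita (1.11), were higher in Met1. The Cd74 and Ciita calls (adjusted p = 0.0379 and 0.0485) both ended without NDL replicate 1, any 1 Met1 array, or SSM2 replicate 2 or 3 (up to 0.116 and 0.151), and that of Ciita without NDL replicate 2. Without each of the former arrays 1 member was higher, and 6 were without SSM2 replicate 1. Between NDL and SSM2 the class II list had a median of 0.01 and a mean of -0.41, and 2 members were lower without SSM2 replicate 3.

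Immune checkpoint genes were lower in NDL than in Met1 in 7 of 25 measured members and higher in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.914 with an estimated correlation). Vtcn1, which encodes the inhibitory B7 family ligand B7-H4, was higher (3.71), as was Lag3 (0.54). The ectoenzyme Nt5e, which makes adenosine, was lower (-2.88). Cd274, which encodes PD-L1, was lower (-1.52, adjusted p = 0.0252) but had an adjusted p = 0.0909 without NDL replicate 1, and Havcr2, which encodes TIM-3 (-1.65, adjusted p = 0.0144), lost its call without NDL replicate 1, NDL replicate 2 or Met1 replicate 3 (adjusted p from 0.0518 to 0.0561). The lower members numbered 3 without NDL replicate 1, NDL replicate 2 or Met1 replicate 3, and 4 without Met1 replicate 1, Met1 replicate 2 or SSM2 replicate 2. T cell markers were lower in NDL than in Met1 in 2 of 17 members, Cd3g (-1.32, adjusted p = 0.0224) and Cd8a (-0.93, adjusted p = 0.018), and these were higher in Met1 than in SSM2 (1.52 and 1.05), with 2 adjusted over the list alone each time (adjusted p = 0.914 with an estimated correlation). In the NDL and Met1 comparison, Cd3g lost its call without NDL replicate 1, Met1 replicate 2 or Met1 replicate 3 (adjusted p up to 0.0908) and Cd8a without Met1 replicate 2 or 3 (up to 0.0665). In the Met1 and SSM2 comparison, both lost it without Met1 replicate 2, Met1 replicate 3 or SSM2 replicate 2 (up to 0.0682 and 0.0561).

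Of 23 measured fibroblast and matrix genes, 8 were higher in NDL than in Met1, led by Thbs2 (2.32), Col1a1 (2.14) and Col1a2 (2.08), and 4 were lower, Dpt (-3.02), the receptor Pdgfra (-2.53), Col6a1 (-1.83) and Col6a2 (-1.08). Adjusted over the list alone these were also 8 and 4 (adjusted p = 0.92 with an estimated correlation). The higher members numbered 5 without NDL replicate 1. The list median was 0.517 and stayed between 0.468 and 1.01 over the alternatives, the fit without NDL replicates 1 and 2 among them. Against SSM2, 8 members were lower in Met1, with Dcn (-3.89), Tnc (-2.84) and Mfap5 (-2.53) first, and the 4 just named, Dpt (1.84), Col6a1 (1.78), Pdgfra (1.54) and Col6a2 (1.13), were higher (11 lower and 4 higher adjusted over the list alone; adjusted p = 0.914 with an estimated correlation). The lower members numbered 5 without NDL replicate 1, Met1 replicate 3 or SSM2 replicate 1 and 4 without Met1 replicate 1 or SSM2 replicate 2, and the higher members 2 without NDL replicate 1, any 1 Met1 array or SSM2 replicate 2. Endothelial markers in NDL were lower than in SSM2 in 4 of 19 members, the lymphatic marker Lyve1 (-1.77), Emcn (-1.34), Vwf (-0.87) and Pecam1 (-0.79), also 4 adjusted over the list alone (adjusted p = 0.914 with an estimated correlation). Lyve1 lost its call without NDL replicate 1 or SSM2 replicate 2 (adjusted p up to 0.0611) and Emcn without SSM2 replicate 1 or 2 (up to 0.0582); 2 members were lower without SSM2 replicate 2 and 7 without SSM2 replicate 3. The SSM2 arrays varied most in several of these lists: the fibroblast list mean was 9.75, 9.02 and 8.45 and the interferon list mean 8.60, 7.92 and 6.87 in SSM2 replicates 1 to 3. The list means for adipocytes (7.78, 6.98 and 5.88), neutrophils (7.05, 6.20 and 5.28), macrophages (8.88, 8.35 and 7.75), mast cells and eosinophils (5.70, 5.20 and 4.81) and endothelial cells (7.22, 6.93 and 6.71) fell in the same order.

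**Figure D3:**
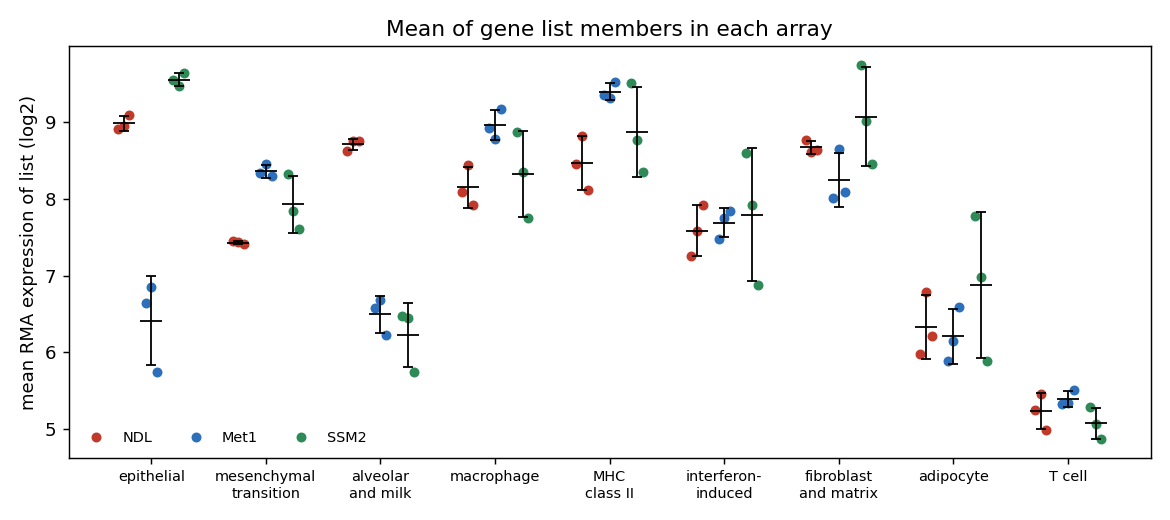
Mean log2 RMA signal of the measured members of 9 gene lists (y axis) in each array, with NDL in red, Met1 in blue and SSM2 in green; bars give the mean ± SD of 3 arrays. The epithelial list mean was 6.41 ± 0.58 in Met1, against 8.99 ± 0.10 in NDL and 9.55 ± 0.09 in SSM2.

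Across the 108 tests of 36 lists in 3 comparisons, camera with an estimated correlation passed 0 at an adjusted p of 0.05, with 8 at an unadjusted p under 0.05 and a smallest adjusted p of 0.326. With the preset correlation camera passed 26 (42 unadjusted), and fry, which asks whether a list's genes move one way without comparing them with other genes, passed 20 (27 unadjusted). The calls with the preset correlation were thus all lost with the estimated one. In fry the adjusted p was 0.000541 for epithelial genes and 0.000379 for milk genes between NDL and Met1, and 0.000425 for ERK outputs between NDL and SSM2. The median, the mean and the camera direction did not all have 1 sign in 15 of the 108 tests. Between NDL and Met1 these were the cytokine receptor and STAT5 feedback genes (median -0.34, mean 0.08), endothelial markers and cholesterol synthesis genes. Between NDL and SSM2 they were the ErbB (0.10 and -0.06), cytokine feedback, MHC class II, regulatory T cell, dendritic cell, proliferation, immediate early, p53 target (0.15 and -0.23) and sex chromosome lists, and between Met1 and SSM2 the muscle, keratinocyte and blood cell lists.

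Each line had genes that stood above or below both other lines. NDL was highest for Chil1, Clca3a2, Wfdc18, Cd177, Ceacam10 and Tc2n, and lowest for Ptgs2, Steap4, Ltbp1, Rgs2 and Prdx4 (Rgs2 -2.65 against Met1 and -3.91 against SSM2), and for Tiparp, whose call against SSM2 (adjusted p = 0.016) ended without NDL replicate 1 (0.0674) and NDL replicate 2 (0.0548). Met1 was highest for Bpifb1, Bmp2, Ptx3, S100a4, Cdh2 and Wif1, and lowest for Erbb3, Krt8, Krt7, Tmc4, the adhesion gene Ceacam1 (-4.17 against SSM2) and Socs2, a feedback inhibitor of cytokine signalling (-4.29 against SSM2). SSM2 was highest for Krt19, Itih2, Cxcl15, Sprr1a, Tph1 and Clca1, and lowest for Etv1, Itga8, Stac2, Mme, Trib2 and Adgrl3 (the latter 3.53 higher in NDL and 3.32 higher in Met1). The moderated F-test over the 3 lines passed 5007 of 19938 genes (25.1%), and 8311 without NDL replicate 3.

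Genes highest in 1 line numbered 1023 for NDL, 815 for Met1 and 381 for SSM2, and genes lowest numbered 716, 435 and 450. Independent lists of the same sizes would share 166, 145 and 71 genes, and 154, 83 and 132. Data simulated with no difference in any gene gave a mean of 0 in 20 simulations. That setting differs from the data, where many genes pass in each contrast. It does not show how many genes that differ in 1 contrast pass the other through shared arrays. Both comparisons of a line share its arrays, and the part of the excess that this adds cannot be split off. With both differences at least 2-fold, NDL was highest for 400 and lowest for 289 genes, Met1 for 360 and 197, and SSM2 for 211 and 167. Without NDL replicate 3 the genes highest in NDL numbered 2475 and those lowest in NDL 2044. Leaving out NDL replicate 1 gave 299 lowest in NDL, 535 highest in Met1, 230 highest in SSM2 and 298 lowest in SSM2, and leaving out NDL replicate 2 gave 432 lowest in NDL. Leaving out Met1 replicate 1 gave 419 lowest in NDL, 478 highest and 254 lowest in Met1, and 212 highest and 247 lowest in SSM2. The same counts without Met1 replicate 2 were 408, 497, 287, 222 and 260. Without Met1 replicate 3, 427 genes were lowest in NDL and 497 highest in Met1. Without SSM2 replicate 2, 299 genes were lowest in SSM2, and without SSM2 replicate 3, 572 were highest in SSM2.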

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

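Quantile normalisation, the gene-by-gene array weights and leaving out NDL replicates 1 and 2 were chosen after the data were seen. No named gene difference reversed under the alternatives compared gene by gene (529 differences, 320 of them called, or 505 and 417 under the signal filters). Treat, the test of every feature, the adjustment over 3 contrasts and the fits of 2 lines were compared by counts alone. The filters on signal, the intensity trend, all scalings and the adjustment over 3 contrasts left each count of differing genes within 1.5 times its value. The share of calls between NDL and Met1 that were higher in NDL was 46.4% as deposited and 53.2%, 55.2% and 55.8% after cyclic loess, equal medians and quantile normalisation. The titles do not pair the replicates, and same-number arrays were not consistently alike (r of residuals across genes from -0.347 to 0.288). With the replicate number as a block, the counts were 4326 for the F-test and 3343, 2779 and 1968 for NDL against Met1, NDL against SSM2 and Met1 against SSM2, with 35 named calls lost and 10 gained.

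With each array left out in turn, counts ranged from 3354 to 8311 for the F-test, 2371 to 6631 for NDL against Met1, 1873 to 7018 for NDL against SSM2 and 1360 to 2754 for Met1 against SSM2, and for differences of at least 2-fold from 1417 to 2680, 1106 to 2582 and 947 to 1322 (1135, 834 and 1102 without NDL replicates 1 and 2). Genes highest and lowest ranged from 705 to 2475 and 299 to 2044 for NDL, 478 to 893 and 254 to 513 for Met1, and 212 to 572 and 247 to 537 for SSM2. List tests ranged from 0 to 0. Of 115, 111 and 94 named calls in the 3 contrasts, 31, 28 and 25 ended in at least 1 of these 9 fits. Leaving out both NDL replicates 1 and 2, so that the lone NDL array is assumed to vary like the others, gave 2936 for the F-test, 1702 and 1190 for the NDL contrasts, and 532, 154, 421, 282, 172 and 248 genes highest and lowest in NDL, Met1 and SSM2, from fewer arrays; 109 named calls were lost. The cause of the larger counts without NDL replicate 3 was not tested; NDL replicates 1 and 2 correlated at r = 0.986 across genes.

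Array weights by the planned default, whose search stopped before its tolerance, gave 4007 genes for Met1 against SSM2. The gene-by-gene weights, tried for that reason, gave 11146 for the F-test and 10125, 7742 and 3726 for the contrasts. Genes highest and lowest in NDL, Met1 and SSM2 then numbered 3368, 2353, 1354, 859, 833 and 767. These weights were 3.62, 0.513 and 0.237 for NDL replicates 1 to 3, against 0.46, 0.642 and 0.311 by the default. The NDL mean thus rested largely on replicate 1. Whether this caused the larger counts was not tested. Testing against a minimum fold of 1.5 gave 871, 644 and 542, by construction a stricter call. With 2 lines alone in the fit, NDL against SSM2 gave 1755, from fewer arrays. That fit also left out Met1, whose median SD over genes was 0.113, against 0.203 in NDL and 0.177 in SSM2. In the main fit Met1 enters the shared estimate of the spread. Whether the number of arrays or their spread caused the lower count was not tested. List tests passed in 26 cases with the preset correlation, which replaces the estimated one, and in 20 with fry, which tests a list alone and not against other genes. Signal over background limits the size of 18 of the 320 called named differences, whose lower group mean lay under the 25th percentile of signal (4.58). In simulated data, known log2 changes of 0.5 were recovered in 14%, 4% and 8% of genes. The order is NDL against Met1, NDL against SSM2 and Met1 against SSM2. For changes of 1, which is 2-fold, the shares were 64%, 72% and 44%. A gene that did not pass is therefore not shown to be equal.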

Other observations

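The tests of the share of tumour cells in Met1, of NDL replicates 1 and 2 as the source of the epithelial difference, and of whole-chromosome gain or loss were chosen after the result was seen. Fatty acid synthesis genes were higher in NDL than in Met1 in 6 of 20 measured members, among them Me1 (log2 difference 1.59), the regulator Srebf1 (1.51) and the desaturase Scd2 (1.39), and lower in 2, Fads1 (-1.22) and Fasn (-0.91); adjusted over the list alone these were 10 and 3 (adjusted p = 0.914 with an estimated correlation). In NDL against SSM2, 4 were higher, led by Srebf1 (2.43), the acetyl-CoA synthetase Acss2 (1.89) and Elovl5 (1.42), and 2 lower, Elovl7 (-1.19) and Gpam (-0.75), or 5 and 2 adjusted over the list alone (adjusted p = 0.914 with an estimated correlation). The lower members numbered 0 without NDL replicate 1, NDL replicate 2 or SSM2 replicate 1, and 1 without any 1 Met1 array or SSM2 replicate 2 or 3. Hypoxia and glycolysis genes were lower in NDL than in Met1 in 6 of 22 measured members (6 adjusted over the list alone, adjusted p = 0.914 with an estimated correlation). Fewer passed without NDL replicates 1 and 2. The angiogenic factor Vegfa (-2.29), the prolyl hydroxylases P4ha2 (-2.09) and P4ha1 (-1.84) and the carbonic anhydrase Car9 (-1.75) came first. Egln3 went the other way without passing, at 11.31, 11.31 and 11.34 in NDL against 9.787, 9.787 and 9.78 in Met1. Its SSM2 arrays stood at 9.326, 6.866 and 9.163, and the shared estimate of the spread takes them in. The lack of a call for Egln3 therefore does not show that NDL and Met1 were alike. Against SSM2, 4 members of the list were higher and 2 lower in NDL. The list median in that comparison was -0.167, and it ranged from -0.264 to 0.194 over the alternatives, so its sign was not stable.

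Of 41 chemokines, cytokines and growth factors for immune cells, 2 were higher and 7 lower in NDL than in Met1, 5 higher and 1 lower in NDL than in SSM2, and 6 higher and 2 lower in Met1 than in SSM2 (3 and 8, 5 and 1, and 6 and 2 adjusted over the list alone). As a set the list had adjusted p = 0.914, 0.914 and 0.922 with an estimated correlation. The 7 lower numbered 4 without NDL replicate 1 or Met1 replicate 3, the 5 higher numbered 3 without NDL replicate 1 or 2, and the 6 higher numbered 3 without SSM2 replicate 2 or 3. The lower members numbered 2 in NDL against SSM2 without SSM2 replicate 3, and 1 in Met1 against SSM2 without NDL replicate 2, Met1 replicate 1 or 2, or SSM2 replicate 1 or 2. The alarmin Il33 was higher in SSM2 than in NDL (-4.33) and Met1 (-4.07). Tgfb3 was higher in NDL than in Met1 (2.45) and SSM2 (2.84). The macrophage growth factor Csf1 was higher in Met1 than in SSM2 (2.04) and lower in NDL than in Met1 (-1.37). Outside that list, Wif1 was highest in Met1 (-3.13 in NDL against Met1, 3.81 against SSM2). Xist, transcribed from the inactive X chromosome, was lower in Met1 than in SSM2 (-2.14, adjusted p = 0.0282) at 8.91, 8.95 and 9.34 against 11.18, 10.45 and 11.98, a call that ended without NDL replicate 1, any 1 Met1 array, or SSM2 replicate 1 or 3 (adjusted p from 0.0536 to 0.0996).

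Chance was weighed by splitting the arrays in other ways. Splits of the 9 arrays into 3 groups of 3 numbered 100, drawn from 280 with the real one always included. Of these, 1 (the real one) gave as many genes in the F-test (5007, against at most 1132 in the others). The same held for genes highest or lowest in a group (3820 against 991). Arbitrary groupings of the arrays thus rarely gave such counts. The splits treat arrays as independent samples, which the labels do not state. They cannot separate the line from a tumour, animal or batch shared within it. For each pair of lines the 10 splits of 6 arrays are too few for a share under 0.05. The real counts were the only ones as large, 1 of 10 each time, with 3814 against at most 0, 3364 against at most 1, and 2356 against at most 0 in the other splits.

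Erbb2 was 3.17 above the mean of the other lines in NDL. A gain of the chromosome segment around it might contribute, beside the transgene that NDL is known to carry. The 10 nearest measured genes with a signal above the median of all features had a median difference of 0.587 (95% interval over genes 0.13 to 1.1). Csf3 (1.16), Stard3 (1.10), Mien1 (0.86), Pgap3 (0.59), Ormdl3 (0.58), Ppp1r1b (0.48) and Psmd3 (0.17) were above both lines. Grb7 (1.21) came from 2.53 against Met1 and -0.11 against SSM2, and Cdk12 (-0.22) and Med1 (-0.35) were below both lines. The interval holds the set bound of 0.5, so a gain and its absence cannot be told apart here. The Erbb2 difference itself lay above that of each of the 10 genes, the largest of which was 1.21 (Grb7).

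Epithelial genes were lower in Met1 than in both other lines. A smaller share of tumour cells in the Met1 samples, with the other cell types in unchanged proportions, would raise the markers of all those types alike. The macrophage and endothelial lists moved apart, which argues against that form of the explanation as the whole cause. More macrophages added to the samples would move them apart too, but would lower endothelial and epithelial markers alike. The epithelial medians in Met1 were -2.92 against NDL (95% interval over genes -3.15 to -2) and -2.99 against SSM2 (-3.46 to -2.67). The endothelial intervals given next lay well above these, which argues against added macrophages as the whole cause. Macrophages in place of tumour cells alone would leave endothelial markers unchanged, so that form stays open. The endothelial medians in Met1 were -0.07 against NDL (95% interval over genes -0.205 to 0.101) and -0.16 against SSM2 (-0.466 to -0.0552), and the macrophage medians 1.20 (0.637 to 1.37) and 1.05 (0.443 to 1.21). The gap between the list means was 0.843 larger in Met1, a comparison chosen once the macrophage rise was known, so its size adds no support of its own. It replaced a first version on the fibroblast list, whose median against SSM2 was -1.26 with an interval from -1.6 to 0.02. The signal distribution of NDL replicates 1 and 2 is argued against too, since the list median between NDL and Met1 was 3.03 without them and the SSM2 comparison does not use them. A change in the macrophages themselves stays open, and so does a difference in the identity of the tumour cells, which was not tested.

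Genes of single chromosomes shifted together between lines. Of 60 shifts computed, 40 passed an adjusted p of 0.05 in a permutation of genes (smallest p 1e-04, the smallest 10000 permutations can give). The permutation treats genes as independent and does not measure the spread between samples of a line, so its p may be too small. A shift of -0.034 passed too (chromosome 2 in Met1 against SSM2, adjusted p = 0.0423 in this permutation). The comparisons share arrays, so the 60 shifts are not separate results. Of the 40, 14 were at least 0.2 in size. Among them were chromosome 13 in NDL against SSM2 (-0.61) and Met1 (-0.48) and chromosome 14 in NDL against Met1 (-0.55). Chromosome 19 in Met1 against SSM2 (-0.41) was another. The chromosome 13 shift against SSM2 was -0.433 without NDL replicates 1 and 2 and -0.606 (95% interval -0.714 to -0.519) against genes matched on signal, which argues against both as the whole cause. Gain or loss of whole chromosomes in the tumour cells may be a candidate explanation, and it stays open. Of 17 comparisons chosen because the genes of the first part of the chromosome shifted by at least 0.2, the second part shifted the same way by at least 0.5 times as much in 11, and chromosome 15 in Met1 against SSM2 had parts that shifted apart (-0.26 and 0.07). Differences in strain background between the lines were not tested.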
